A study of Mus musculus with 12 samples.

How the data were processed

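Messenger RNA was measured by sequencing in lymph nodes draining tumours of female C57BL/6J mice on day 18. The mice carried B16F10-OVA tumours, a mouse melanoma line that expresses ovalbumin as a model antigen. The labels put the 12 libraries into 3 treatment groups of 4, named PBS (the buffer control), IPSPlipo and IPSPlipo+US. The labels do not spell out IPSPlipo or US, and the names are used as given. Per the labels' protocols, total RNA was extracted with the RNAsimple kit, polyadenylated RNA was enriched on oligo(dT) beads and libraries were built with the VAHTS Universal V10 RNA-seq kit. Nothing in the labels states that each library came from a separate mouse, so p-values measure the spread between these libraries.

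The deposited values are raw counts of reads per Ensembl gene, 1 column per library, and were not normalized by the authors as far as the file shows. Per the submitters' processing notes, fastp, HISAT2 and featureCounts were used on the GRCm39 genome. Their versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from a gene and an overlapping or antisense gene may therefore be mixed, and counts of near-identical copies (immunoglobulin segments and constant regions, histone genes, haemoglobin genes, Ly6c and Klra genes, guanylate-binding proteins) are uncertain as to which copy they came from. The file gives 56941 gene identifiers and no coordinates. Symbols, gene types, exon lengths and GC content were looked up by identifier in the GENCODE M21 annotation. That annotation is on another build, GRCm38, so no coordinates are given. A symbol was found for 52000 identifiers, and 5.57% of all counts fell on identifiers without one. No row lacked a gene identifier.

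Totals ranged from 12816533 to 21699599 counts per library. At such depth 1 CPM corresponds to more than 10 counts, and counts without molecular identifiers are not independent molecules, so limits set from counts cover counting error only. Pairs of libraries of the same group differed by far more than sampling noise, with a chi-square per degree of freedom of 10.9 to 60.0 over 18 pairs, and no library was counted as a copy of another.

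Changes between groups were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups and its defaults, which left 21182 genes, 876 of them without a symbol. Libraries were scaled by TMM. All 12 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest, two-sided) with the group as the only term, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. A joint test on both group coefficients asked whether any group differed. The square root of the common dispersion was 0.232. CPM in the text are counts-per-million values on TMM-scaled library sizes, computed from the deposited counts, and are given as mean ± SD with n = 4. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic.

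Before the data were examined, 33 gene lists with 424 genes were fixed for lymph node cell types, vaccine responses and tissues that a dissected node could carry along. All 424 were found and 389 were tested. Lists were tested with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. Adjusted p-values of lists cover the 33 lists of a comparison. Several genes sit on more than 1 list. Genes were named by a rule that was also fixed beforehand. It took, per comparison, up to 8 genes in each direction with the largest fold change among those past the threshold with a mean of at least 1 CPM and no overlap between the groups' libraries. Gene segments of immunoglobulins and T cell receptors and predicted genes were counted but not named. It added up to 3 members of each list with a call or a changed member, and 13 genes chosen in advance (Cd8a, Gzmb, Prf1, Ifng, Foxp3, Cxcl9, Cxcl10, Cd274, Jchain, Lyve1, Mki67, Pmel and 1 that is not reported here, which counts over genes and lists include). Where no gene passed, the 3 genes with the smallest p were named. Where a count of 5 or fewer is given its genes are also named, and those outside the rule were chosen after their values were seen. Shares of counts on mitochondrial, immunoglobulin and haemoglobin genes were compared by exact two-sided permutation tests. With 4 libraries against 4 the smallest p these tests can give is 0.0286.

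The scripts were tested on simulated counts drawn from the real means and library sizes with known changes. At a 2-fold change, edgeR recovered 45.5% of changed genes in the simulation of IPSPlipo against PBS, 44.4% for IPSPlipo+US against PBS and 46.2% for IPSPlipo+US against IPSPlipo. At a 4-fold change it recovered 79.4%, 83.9% and 83.1%, and at 1.5-fold 18.2%, 29.2% and 13.4%, in the same order. These runs covered 20728, 20754 and 20702 genes. False calls made up 8.80%, 3.91% and 2.63% of all calls, against 16.5%, 15.7% and 14.7% for DESeq2. Camera called the 3 lists shifted by 1.5-fold and none of 29 others in each simulation, with the preset and with an estimated correlation. Genes were drawn independently there, so these runs do not test the preset correlation on lists whose genes move together. In the real data the estimated correlation reached 0.857, in the adipocyte list.

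Alternatives chosen before the data were examined were DESeq2 size factors, library size without scaling, no filter, a stricter filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, robust dispersion estimates, a fit of only the groups compared, the replicate number as a block, a minimum fold change of 2, immunoglobulin genes left out, and each library left out in turn. After the data were seen, 5 more were added for the counts of changed genes. They were PBS 3 and PBS 4 left out together, the log2 share of counts on the most abundant identifier as a covariate, the mean level of the adipocyte list as a covariate, a correction for GC content and exon length, and thinning of all libraries to the smallest total.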

Results

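Transcript levels were measured by poly(A) RNA sequencing in tumour-draining lymph nodes of female C57BL/6J mice on day 18. All mice carried B16F10-OVA tumours. The 12 libraries formed 3 groups of 4: PBS, IPSPlipo and IPSPlipo+US. The title of the series places the work in cancer vaccination with acoustic cavitation in the lymph node. The design therefore asks what IPSPlipo changes in the draining node, what IPSPlipo+US changes, and what the addition of US changes over IPSPlipo alone.

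Total counts per library ranged from 12816533 to 17884712 in PBS, from 15888397 to 20132553 in IPSPlipo and from 18988626 to 21699599 in IPSPlipo+US. The IPSPlipo+US libraries were deeper than the PBS libraries (exact permutation test, two-sided, p = 0.0286, the smallest p that 4 against 4 can give). Each library had counts for 24917 to 28476 genes. The most abundant gene identifier, ENSMUSG00000118642, has no symbol in the annotation used. It took 4.24%, 5.30%, 7.99% and 11.7% of the counts in PBS 1 to 4. In IPSPlipo its share was 3.76 ± 1.11% and in IPSPlipo+US 2.95 ± 0.424%. The difference between IPSPlipo+US and PBS was larger than the spread (exact permutation test, p = 0.0286), and that between IPSPlipo and PBS was not (p = 0.0857). These comparisons of the identifier were added after the data were seen. On the first principal component (28.6% of the variance), PBS 3 and PBS 4 lay farthest out, at -45.8 and -90.1. PBS 1 and PBS 2 lay at -14.2 and -20.2, next to IPSPlipo 1 and IPSPlipo 2 at -8.65 and -14.3. IPSPlipo 3, IPSPlipo 4 and all 4 IPSPlipo+US libraries lay between 28.1 and 43.0.

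**Figure D1:**
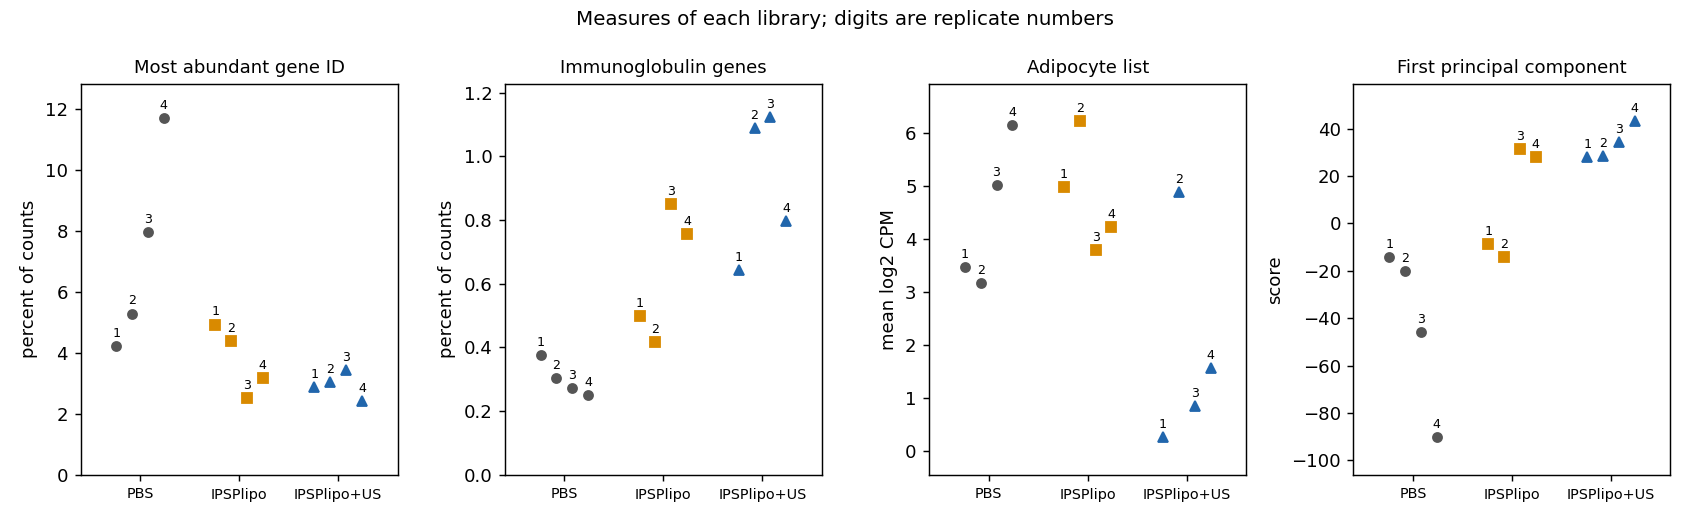
Each point is a library, with its replicate number, in the groups PBS, IPSPlipo and IPSPlipo+US. The panels give the percent of counts on the most abundant gene identifier, the percent on immunoglobulin genes, the mean log2 CPM of the adipocyte list and the score on the first principal component. PBS 3 and PBS 4 had 7.99% and 11.7% of their counts on the most abundant identifier, above the other 10 libraries.

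Immunoglobulin genes took 0.301 ± 0.0540% of counts in PBS, 0.631 ± 0.206% in IPSPlipo and 0.913 ± 0.232% in IPSPlipo+US (n = 4). All 4 libraries of each treated group lay above all 4 PBS libraries (exact permutation test, p = 0.0286 for each, 0.0643 after adjustment over 9 comparisons). IPSPlipo+US did not separate from IPSPlipo (exact p = 0.143, adjusted 0.214). Mitochondrial transcripts took 1.53 ± 0.302% in PBS, 1.12 ± 0.144% in IPSPlipo and 1.15 ± 0.129% in IPSPlipo+US (exact permutation test, p = 0.0286 for each treated group against PBS, adjusted 0.0643). Haemoglobin transcripts took 0.00394 ± 0.00386% in PBS and 0.000843 ± 0.000297% in IPSPlipo+US (exact permutation test, p = 0.0571, adjusted 0.103).

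The first comparison asked what IPSPlipo changed relative to PBS. Genes higher in the IPSPlipo nodes included some induced by interferon, cytotoxic granule genes, immunoglobulin genes and some of macrophages and monocytes. Gzma (ENSMUSG00000023132) and Gzmb (ENSMUSG00000015437), granule proteases of cytotoxic T cells and natural killer cells, rose 5.90-fold (9.40 ± 4.62 against 1.55 ± 0.806 CPM) and 5.74-fold (4.62 ± 1.60 against 0.790 ± 0.319 CPM). Ighg2c (ENSMUSG00000076612), the constant region of an immunoglobulin G isotype, rose 10.2-fold, from 46.3 ± 27.3 to 473 ± 373 CPM. Ccl22 (ENSMUSG00000031779), a chemokine of mature dendritic cells that attracts regulatory T cells, fell from 66.2 ± 17.8 to 27.3 ± 8.66 CPM. In all, 100 of 21182 genes changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 83 higher and 17 lower. Among the 83 were 9 immunoglobulin gene segments.

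The named genes that rose most also included Saa3 (ENSMUSG00000040026), an acute-phase serum amyloid, at 9.79-fold, and Slfn4 (ENSMUSG00000000204) at 7.57-fold. Siglece (ENSMUSG00000030474), an inhibitory receptor of myeloid cells, rose 6.93-fold and Sirpb1b (ENSMUSG00000095028) 4.39-fold. Fcgr1 (ENSMUSG00000015947), the high-affinity immunoglobulin G receptor, rose 4.24-fold. Adjusted p-values of these genes and of Gzma, Gzmb and Ighg2c by edgeR lay between 0.0188 and 0.0398. Among the genes that fell, Ppbp, a platelet chemokine, went from 4.57 ± 4.46 to 0.247 ± 0.104 CPM, and Oit1 to 0.377 of its PBS level. Tsc22d3, a glucocorticoid-induced gene, fell from 203 ± 17.0 to 94.2 ± 25.6 CPM, and Nr4a1, an immediate early nuclear receptor, from 55.4 ± 19.4 to 27.9 ± 3.75 CPM. Epb41l4aos, Trim7 and Lmbr1l fell to between 0.601 and 0.711 of their PBS level. Single libraries moved some of these changes by over 1.5 times. The log2 fold change of Saa3 was 2.69 without IPSPlipo 4 (3.29 with all libraries). That of Slfn4 was 2.32 without IPSPlipo 3 (2.92) and that of Ppbp -3.45 without PBS 4 (-4.17). Calls rested on single libraries for all named genes. Of the 27 named calls in this comparison, 0 held without PBS 2, PBS 3 or IPSPlipo 4. Without PBS 4 only that of Oas3 held, and without IPSPlipo 3 only that of Gzma.

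By list, camera with the preset correlation called 14 of 33 lists higher and 3 lower in IPSPlipo against PBS. With an estimated correlation none of the 17 calls held, and the value for each list follows as its adjusted p with an estimated correlation. Fry, which does not compare a list with other genes, called 10 lists, 9 of the 17 and that of melanoma and melanocytes. It did not call those of plasma cells, regulatory T cells, mature dendritic cells, reticular stroma, matrix, lymphatic endothelium, proliferation and erythrocytes. Of 22 tested genes of the type I interferon response, 4 rose over all genes and 21 adjusted over the list alone, with a median log2 fold change of 1.25 (estimated-correlation adjusted p = 0.270). Isg15, a ubiquitin-like interferon-induced protein, rose 3.93-fold, Oas3, an antiviral nucleotide synthetase, 2.92-fold, Ifih1, a sensor of double-stranded RNA, 2.31-fold, and Ifi44 3.95-fold. Of 17 interferon gamma response genes, 1 rose (Gbp2, 1.67-fold) and 8 adjusted over the list alone (estimated-correlation adjusted p = 0.270). Of 13 genes of MHC class I presentation, 2 rose and 4 adjusted over the list alone (estimated-correlation adjusted p = 0.279). They were B2m, the light chain of class I molecules, at 1.90-fold and the chaperone Calr at 1.52-fold, joined over the list alone by Pdia3 and Psmb8.

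Of 14 macrophage genes, 3 rose and 12 adjusted over the list alone, with a median of 0.83 (estimated-correlation adjusted p = 0.270). They were Fcgr1, Csf1r, the receptor for macrophage colony-stimulating factor (280 ± 86.2 against 146 ± 14.9 CPM), and the complement gene C1qa (1.80-fold). Of 10 monocyte genes, Ly6c2 rose 2.37-fold and 7 changed adjusted over the list alone (estimated-correlation adjusted p = 0.270). None of 5 neutrophil genes passed over all genes and 4 did adjusted over the list alone (Csf3r, Cxcr2, Mmp9 and Ltf). Csf3r was at 2.02-fold (adjusted p = 0.0582), and the list had an estimated-correlation adjusted p = 0.238. Of 10 natural killer cell genes, 2 rose (Gzma and the receptor Ncr1, 3.91-fold) and 5 adjusted over the list alone, with Klre1, Klrk1 and Klra7 (estimated-correlation adjusted p = 0.270). Of 16 cytotoxic effector genes, 2 rose (Gzma and Gzmb) and 6 adjusted over the list alone (estimated-correlation adjusted p = 0.238).

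Of 11 immunoglobulin constant regions, 2 rose (Ighg2c and Igkc, from 214 ± 84.8 to 643 ± 259 CPM) and 9 adjusted over the list alone, with a median of 1.33 (estimated-correlation adjusted p = 0.238). No plasma cell gene of 12 passed over all genes and 8 did adjusted over the list alone, with Xbp1, a regulator of antibody secretion, at 1.82-fold (adjusted p = 0.0614) and Jchain, which joins immunoglobulin M and A, at 3.66-fold (adjusted p = 0.0694). The list's adjusted p was 0.339 with an estimated correlation. No proliferation gene of 22 passed and 9 did adjusted over the list alone, with a median of 0.47 (estimated-correlation adjusted p = 0.415). No member passed over all genes among the reticular stromal, extracellular matrix and lymphatic endothelium lists, whose medians were 0.39, 0.53 and 0.73 (estimated-correlation adjusted p = 0.344, 0.516 and 0.516). Adjusted over the list alone, Cxcl12 and Dcn passed on the reticular list and Mmp14 on the matrix list. The lists called lower were those of regulatory T cells (median -0.26, 0 of 13 members over all genes, Ikzf4 and Ccr8 adjusted over the list alone), mature dendritic cells (median -0.27, with Ccl22 the 1 member of 14 that fell, Fscn1 also lower and Cd86 higher adjusted over the list alone) and erythrocytes (median -1.28, 0 of 5 members). Their estimated-correlation adjusted p-values were 0.362, 0.279 and 0.516. The mean log2 CPM of the erythrocyte list was 1.38, 1.87, 4.15 and 3.25 in PBS 1 to 4 and 0.91, -0.33, 2.87 and 2.34 in IPSPlipo 1 to 4, and the median of that list was 0.33 without PBS 3 and PBS 4, -0.58 without PBS 3, which ended the call, and -1.96 without IPSPlipo 3. Foxp3, the regulator of regulatory T cells, was at 17.6 ± 4.01 CPM against 23.9 ± 2.59 CPM in PBS (adjusted p = 0.249).

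Cd8a was at 145 ± 28.8 CPM in IPSPlipo and 149 ± 26.1 CPM in PBS (adjusted p = 0.935), and the medians of the T cell and follicular B cell lists were -0.01 and -0.06. The sign of the T cell median turned with scaling by library size alone (0.03). Cxcl9, Cxcl10, Mki67, Ifng, Lyve1, Prf1, Pmel and Cd274 did not pass, with adjusted p-values between 0.0739 and 0.485. The remaining lists without a call in this comparison had medians between -0.45 (germinal centre B cells) and 0.42 (melanoma and melanocytes). The blood and high endothelium list had a median of 0.18 and a mean of 0.05, while its test pointed down. The adipocyte list, with a median of 0.12, had no changed member. Its median was 2.11 without PBS 3 and PBS 4 and 2.86 with the share of the most abundant identifier as a covariate. Camera with the preset correlation called it higher in both settings (adjusted p = 0.00612 and 0.000661).

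The count of 100 was 230 without PBS 1, 0 without PBS 2, 0 without PBS 3, 8 without PBS 4, 200 without IPSPlipo 1, 245 without IPSPlipo 2, 9 without IPSPlipo 3 and 2 without IPSPlipo 4 (Hist1h3b and Iglv1, named after their values were seen), 0 without both PBS 3 and PBS 4 or with the share of the most abundant identifier as a covariate, and 1000 (547 higher, 453 lower) with DESeq2. All 100 genes kept their direction without PBS 3 and PBS 4 and with that covariate, with a median change in the direction called of 0.92 and 0.82 on the log2 scale against 1.03, while the median standard error rose from 0.185 to 0.226 and 0.230. These genes were called with all libraries, most or all of which were used again. A kept direction is therefore largely given by their selection. Limma-voom called 6 genes, 5 higher and 1 lower. Of the lists, single libraries ended the calls of mature dendritic cells (PBS 2 or IPSPlipo 4), reticular stroma (PBS 4 or IPSPlipo 4), matrix (IPSPlipo 4), lymphatic endothelium (PBS 4, IPSPlipo 3 or IPSPlipo 4), MHC class I presentation (PBS 1) and erythrocytes (PBS 3, PBS 4 or IPSPlipo 2). Without PBS 3 and PBS 4 those of reticular stroma, lymphatic endothelium and erythrocytes ended, and with the share covariate also those of mature dendritic cells, monocytes and matrix. Calls were also gained, higher in IPSPlipo: adipocytes in both settings, and melanoma and melanocytes without PBS 3 and PBS 4 (camera with the preset correlation, adjusted p = 0.0210). The split was 106 higher and 74 lower after a correction for GC content and exon length, against 83 and 17 without it.

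**Figure D2:**
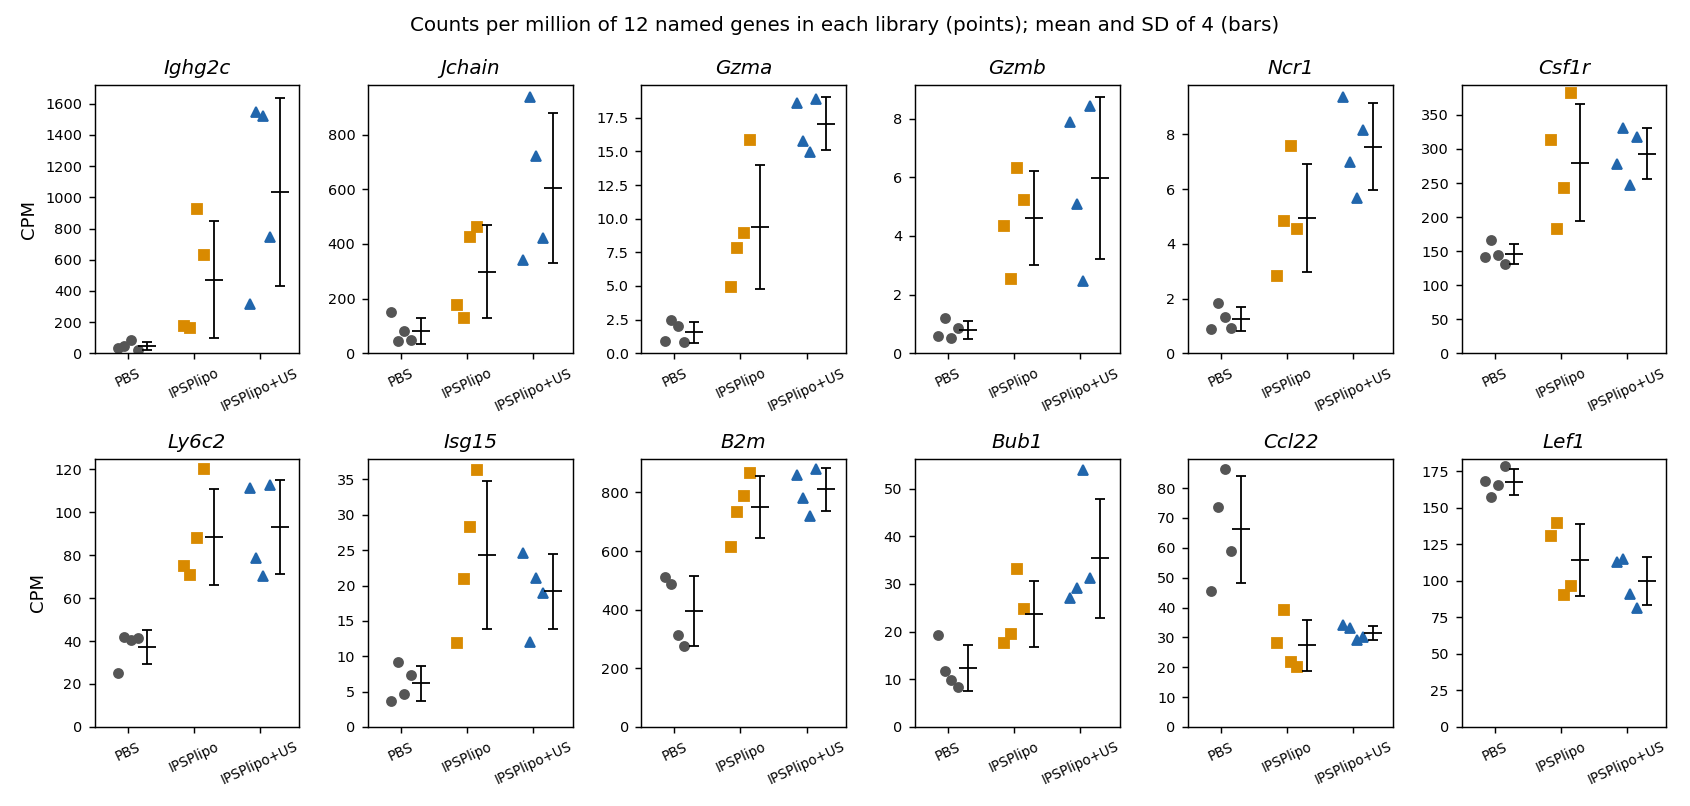
CPM of 12 named genes in each library of PBS, IPSPlipo and IPSPlipo+US, with the mean and SD of 4 libraries beside the points and a linear axis for each gene. For Gzma, the PBS mean was 1.55 CPM, the IPSPlipo mean 9.40 CPM and the IPSPlipo+US mean 17.0 CPM.

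The second comparison asked what IPSPlipo+US changed relative to PBS. Genes higher in the IPSPlipo+US nodes included many of plasma cells, natural killer and cytotoxic cells, macrophages, interferon responses and dividing cells, and haemoglobin genes were among the lower ones. Gzma rose 10.7-fold to 17.0 ± 1.98 CPM and Gzmb 7.44-fold to 5.97 ± 2.77 CPM. Ighg2c rose 22.3-fold to 1034 ± 606 CPM and Jchain (ENSMUSG00000067149) 7.44-fold, from 81.3 ± 48.9 to 605 ± 274 CPM. Lef1 (ENSMUSG00000027985), a transcription factor of naive T cells, fell from 168 ± 8.84 to 99.9 ± 16.4 CPM. In all, 2307 of 21182 genes changed, 1356 higher and 951 lower (edgeR quasi-likelihood test, adjusted p under 0.05). The change was at least 2-fold for 505 of the higher and 128 of the lower genes, and 87 of 193 tested immunoglobulin gene segments were higher and 0 lower.

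The genes with the largest rises included Cdhr2 (ENSMUSG00000034918), which had 0 counts in PBS and 231 in IPSPlipo+US. Set against a floor of 3 counts over the PBS group, it was at least 58.6-fold higher, and at least 32.1-fold without IPSPlipo+US 4, whose loss left 97 of the 231 counts. Fpr1 (ENSMUSG00000045551), a formyl peptide receptor of neutrophils and monocytes, rose 27.4-fold to 2.88 ± 1.35 CPM. The myeloid receptors Siglece and Cd300e (ENSMUSG00000048498) rose 14.5-fold and 11.9-fold, and the immunoglobulin G receptor Fcgr4 (ENSMUSG00000059089) rose 10.9-fold. Saa3 rose 8.12-fold. The genes that fell most were Ppbp (4.57 ± 4.46 to 0.234 ± 0.265 CPM), the haemoglobin genes Hba-a2 and Hba-a1 (3.63 ± 3.17 to 0.496 ± 0.179 CPM for Hba-a2 and, for Hba-a1, to 0.176 of its PBS level), and the adenosine receptor Adora1 (2.12 ± 1.51 to 0.385 ± 0.181 CPM). Stra6, a transporter of retinol, fell to 0.275 of its PBS level, Barhl1 to 0.289, Pdk4, a kinase that restrains glucose oxidation, to 0.295 and Clmn to 0.314. Single libraries moved some of these changes by over 1.5 times. The log2 fold change of Fpr1 was 5.80 without PBS 1 (4.78 with all libraries), of Cd300e 2.93 without IPSPlipo+US 4 (3.58), of Fcgr4 4.07 without PBS 3 (3.44), of Ppbp -3.49 without PBS 4 and -5.38 without IPSPlipo+US 2 (-4.19), and of Hba-a2 -2.14 without PBS 3 (-2.84). The calls of Hba-a2, Hba-a1, Barhl1 and Clmn ended without PBS 3, PBS 4, IPSPlipo+US 3 or IPSPlipo+US 4, and further without IPSPlipo+US 1 (Hba-a2 and Clmn) or IPSPlipo+US 2 (Hba-a1, Barhl1 and Clmn), and that of Adora1 ended without PBS 4 or IPSPlipo+US 4. With the share of the most abundant identifier as a covariate the log2 fold change of Clmn turned to 0.0426. Adjusted p-values of these genes and of Ighg2c and Gzma by edgeR lay between 0.000733 and 0.0378.

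Camera with the preset correlation called 12 lists higher and 2 lower in IPSPlipo+US against PBS, and none of the 14 calls held with an estimated correlation. Fry called 14 lists, 10 of them among camera's 14 (not matrix, lymphatic endothelium, adipocytes or erythrocytes). The other 4 were inhibitory receptors, neutrophils, MHC class I presentation and melanoma and melanocytes. Of 12 plasma cell genes, 9 rose and 11 adjusted over the list alone, with a median of 1.26 (estimated-correlation adjusted p = 0.344). Mzb1 rose 5.23-fold and Txndc5, a protein-folding enzyme, 1.88-fold. Of 11 immunoglobulin constant regions, 9 rose and 10 adjusted over the list alone, among them Igkc at 4.82-fold and Ighm, from 871 ± 31.6 to 1704 ± 269 CPM (estimated-correlation adjusted p = 0.274). Of 10 natural killer cell genes, 6 rose and 7 adjusted over the list alone, with Ncr1 at 5.98-fold and the receptor Klra7 at 4.51-fold (estimated-correlation adjusted p = 0.307). Of 16 cytotoxic effector genes, 8 rose, also 8 adjusted over the list alone. They included Cx3cr1, a chemokine receptor of effector cells and monocytes, at 2.25-fold (estimated-correlation adjusted p = 0.274). Prf1, the pore-forming perforin, rose 1.61-fold (adjusted p = 0.0178), a call that ended without PBS 2, PBS 4 or IPSPlipo+US 1. Ifng was at 0.479 ± 0.463 CPM against 0.204 ± 0.144 CPM and did not pass (adjusted p = 0.339).

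Of 14 macrophage genes, 10 rose, and 11 rose and 1 (Cd163) fell adjusted over the list alone (estimated-correlation adjusted p = 0.344). Adgre1, the macrophage surface protein F4/80, rose 4.73-fold, C1qc 2.12-fold and Csf1r 2.01-fold. Of 10 monocyte genes, 5 rose and 9 adjusted over the list alone, with Ly6c2 at 2.50-fold, Plac8 at 162 ± 35.4 against 73.9 ± 8.59 CPM, Ms4a4c at 1.87-fold, Chil3 at 4.57-fold and Fn1 (estimated-correlation adjusted p = 0.344). Of 22 type I interferon genes, 11 rose and 20 adjusted over the list alone, with a median of 1.02 and Isg15 at 3.10-fold, Ifih1 at 67.7 ± 9.71 CPM and Rtp4 at 2.57-fold (estimated-correlation adjusted p = 0.444). Of 17 interferon gamma genes, 7 rose and 9 adjusted over the list alone, with Gbp3 at 1.83-fold, Gbp2 at 1.64-fold and Igtp at 1.57-fold (estimated-correlation adjusted p = 0.354). Cxcl9, an attractant of activated T cells, rose 2.22-fold (adjusted p = 0.0138), and Cxcl10, at 2.01-fold, did not pass (adjusted p = 0.108). Of 22 proliferation genes, 14 rose and 20 adjusted over the list alone, with the mitotic genes Bub1 at 2.86-fold, Ccnb1 at 2.54-fold and Ccnb2 at 2.03-fold (estimated-correlation adjusted p = 0.344). Mki67, a marker of dividing cells, rose 2.14-fold. Single libraries ended the calls of Ms4a4c (PBS 3, PBS 4 or IPSPlipo+US 1, 3 or 4), Rtp4 (PBS 3 or IPSPlipo+US 1) and Mki67 (PBS 3 or PBS 4).

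Of 15 reticular stromal genes, 3 rose (Cxcl12 at 1.85-fold, the matrix proteoglycan Dcn at 1.90-fold and Fap at 2.02-fold) and 5 adjusted over the list alone, with Pdgfra and Tnfsf11 (estimated-correlation adjusted p = 0.344). The calls of Dcn and Fap ended without PBS 3, PBS 4 or IPSPlipo+US 4, and that of Fap also without IPSPlipo+US 1, 2 or 3. Of 21 extracellular matrix and remodelling genes, 3 rose and 6 adjusted over the list alone (estimated-correlation adjusted p = 0.548). They were tenascin C, Tnc, at 4.09-fold, the collagen cross-linking enzyme Lox at 3.17-fold and fibronectin, Fn1, at 2.30-fold. The rise of these genes lay mainly in IPSPlipo+US 2 and IPSPlipo+US 4, with Fn1 at 287, 696, 269 and 801 CPM in IPSPlipo+US 1 to 4 and 284 in PBS 1, and their calls ended without either of these libraries and without PBS 2, PBS 3 or PBS 4. The calls of Lox and Fn1 also ended without IPSPlipo 1 or IPSPlipo 3, and that of the list without IPSPlipo+US 2 or IPSPlipo+US 4. Of 11 lymphatic endothelium genes, the hyaluronan receptor Lyve1 (26.1 ± 12.5 to 96.7 ± 68.4 CPM) and Reln (9.90 ± 6.16 to 26.1 ± 10.5 CPM) rose, and 5 adjusted over the list alone, with Mmrn1, Stab1 and Flt4 (estimated-correlation adjusted p = 0.538). Lyve1 was at 42.5, 186, 43.7 and 115 CPM in IPSPlipo+US 1 to 4. Its call ended without PBS 1, PBS 3, PBS 4, IPSPlipo+US 2 or IPSPlipo+US 4, that of Reln without PBS 2, PBS 3, PBS 4 or IPSPlipo+US 2, 3 or 4, and that of the list without PBS 1, PBS 4, IPSPlipo 1, IPSPlipo 3 or IPSPlipo+US 2, 3 or 4. Of 5 erythrocyte genes, 3 fell (Hba-a1, Hba-a2 and Hbb-bt) and, with Hbb-bs, 4 adjusted over the list alone (estimated-correlation adjusted p = 0.444). Without PBS 3 the log2 fold change of Hbb-bt was -2.28 (-3.09 with all libraries) and its call ended, as did that of the list (adjusted p = 0.0575). Without PBS 3 and PBS 4 the list's median was -1.24 against -2.51 (adjusted p = 0.287). The mean log2 CPM of that list was 1.28, 1.13, 0.49 and 0.46 in IPSPlipo+US 1 to 4. The adipocyte list was called lower with a median of -1.79 and no member of 10 past the threshold (estimated-correlation adjusted p = 0.444). Cidec, a lipid droplet protein, was at 4.11 ± 7.14 CPM against 26.9 ± 27.5 CPM, Fabp4, a fatty acid carrier, at 26.5 ± 29.4 against 95.1 ± 72.6, and the lipase Lipe at 24.8 ± 6.08 against 44.2 ± 25.6 (adjusted p = 0.107, 0.124 and 0.117). The mean log2 CPM of the adipocyte list was 0.26, 4.88, 0.84 and 1.57 in IPSPlipo+US 1 to 4 and 3.46, 3.17, 5.02 and 6.13 in PBS 1 to 4. Without PBS 3 and PBS 4 the list's median was 0.06 and its call ended (adjusted p = 0.0542), as with the share of the most abundant identifier as a covariate (median 1.61, adjusted p = 0.898), and the median was -0.87 without PBS 4 and -5.03 without IPSPlipo+US 2.

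Other lists had changed members without a call. Without PBS 3 and PBS 4, camera with the preset correlation called T cells and naive and memory T cells lower (adjusted p = 0.0480 and 0.0158). It called neutrophils and MHC class I presentation higher there (0.00343 and 0.00554). With the share covariate it called naive and memory T cells and blood and high endothelium lower (0.0388 and 0.00629), and MHC class I and class II presentation higher (6.59e-05 and 0.0388). The T cell signalling genes Zap70, Cd6 and Lat fell to 0.641, 0.671 and 0.554 of PBS, while Cd8a was at 127 ± 24.5 CPM against 149 ± 26.1 (adjusted p = 0.394). Of naive and memory T cell genes, Lef1 and Klf2 fell, to 0.596 and 0.723. Of regulatory T cell genes, Ikzf4 and Ccr8 fell to 0.524 and 0.511, Il10, an anti-inflammatory cytokine, rose 2.83-fold, and Foxp3, at 0.700 of PBS, did not pass (adjusted p = 0.0863). The B cell genes Fcrla, Cd79b and Cd79a rose 1.52-, 1.35- and 1.38-fold, while the follicular B cell list had a median of -0.05 and a mean of 0.07. Eaf2, on the germinal centre list, rose 3.73-fold. Of dendritic cell genes, Tlr3 (1.84-fold), Sirpa (1.69-fold) and the costimulatory Cd86 (1.86-fold) rose, and Clec10a and Ccl22 fell to 0.621 and 0.477. On the plasmacytoid list Irf7 (2.40-fold) and Ly6d (1.43-fold) rose and Pacsin1 fell to 0.679. Of 13 class I presentation genes, 4 rose, B2m at 2.05-fold, Calr at 1.54-fold, Pdia3 at 1.62-fold and Psmb8 at 1.21-fold, and on the class II list the protease gene Ctss rose 1.61-fold. The neutrophil receptors Csf3r and Cxcr2 rose 2.44- and 1.82-fold, Icos of follicular helper T cells 1.41-fold, the inhibitory receptor Cd160 1.42-fold and the chemokine Ccl2 3.31-fold, while Tnfaip3 fell to 0.782. The epithelial genes Sbsn and Cdh1 fell to 0.483 and 0.541, and the immediate early genes Fosb and Ier2 to 0.246 and 0.721. Fosb was at 1.52, 5.48, 4.52 and 20.5 CPM in PBS 1 to 4, and without PBS 4 the level was 0.499 of PBS and the call ended. Of 12 fits that each left out a library, calls held in 1 for Cdh1, 2 for Icos, 3 for Ier2 and Cxcr2, 4 for Sbsn, 5 for Cd160 and Lat, 6 for Fosb, Cd79a, Cd79b, Il10, Klf2, Pacsin1 and Tnfaip3, 7 for Ccl2 and Ly6d, 8 for Irf7, Ccr8, Cd6, Clec10a and Zap70, and 9 for Sirpa. Without IPSPlipo+US 4 all of these calls ended, and without PBS 3 all but those of Klf2 and Clec10a. With the share of the most abundant identifier as a covariate Lat and Ier2 turned (log2 fold change 0.132 and 0.0560). Pmel, a melanocyte gene, was at 14.0 ± 1.27 CPM against 16.6 ± 2.58 (adjusted p = 0.356), and Cd274 at 49.5 ± 6.81 against 38.0 ± 7.53 (adjusted p = 0.15). The blood and high endothelium, skeletal muscle and melanoma lists had no changed member, with medians of -0.09, -0.31 and 0.60.

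The count of 2307 fell to 1001 without PBS 3, 1012 without PBS 4, 1477 without IPSPlipo+US 1, 1376 without IPSPlipo+US 3 and 996 without IPSPlipo+US 4, to 4 without both PBS 3 and PBS 4 (Gzma, Hist1h3b, Hist1h3h and Iglv1, 3 of them named after their values were seen), to 134 with the adipocyte level as a covariate and to 0 with the share of the most abundant identifier as a covariate. Without PBS 3 and PBS 4 all 2307 genes kept their direction and their median change in the direction called was 0.53 on the log2 scale, against 0.67 with all libraries. With the adipocyte covariate all 2307 also kept it, with a median of 0.51, and with the share covariate 2236 did, with a median of 0.35. The 2307 genes were called with most or all of the same libraries, so a kept direction is largely given by their selection. Genes called between PBS 3 and PBS 4 and a pair of IPSPlipo+US libraries kept 0.311 to 0.482 of their median change between the others. These other libraries lay outside the comparison that called the genes. All 12 libraries entered its filter, scaling and estimate of the spread. After the correction for GC content and exon length the split was 1075 higher and 1168 lower, against 1356 and 951.

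**Figure D3:**
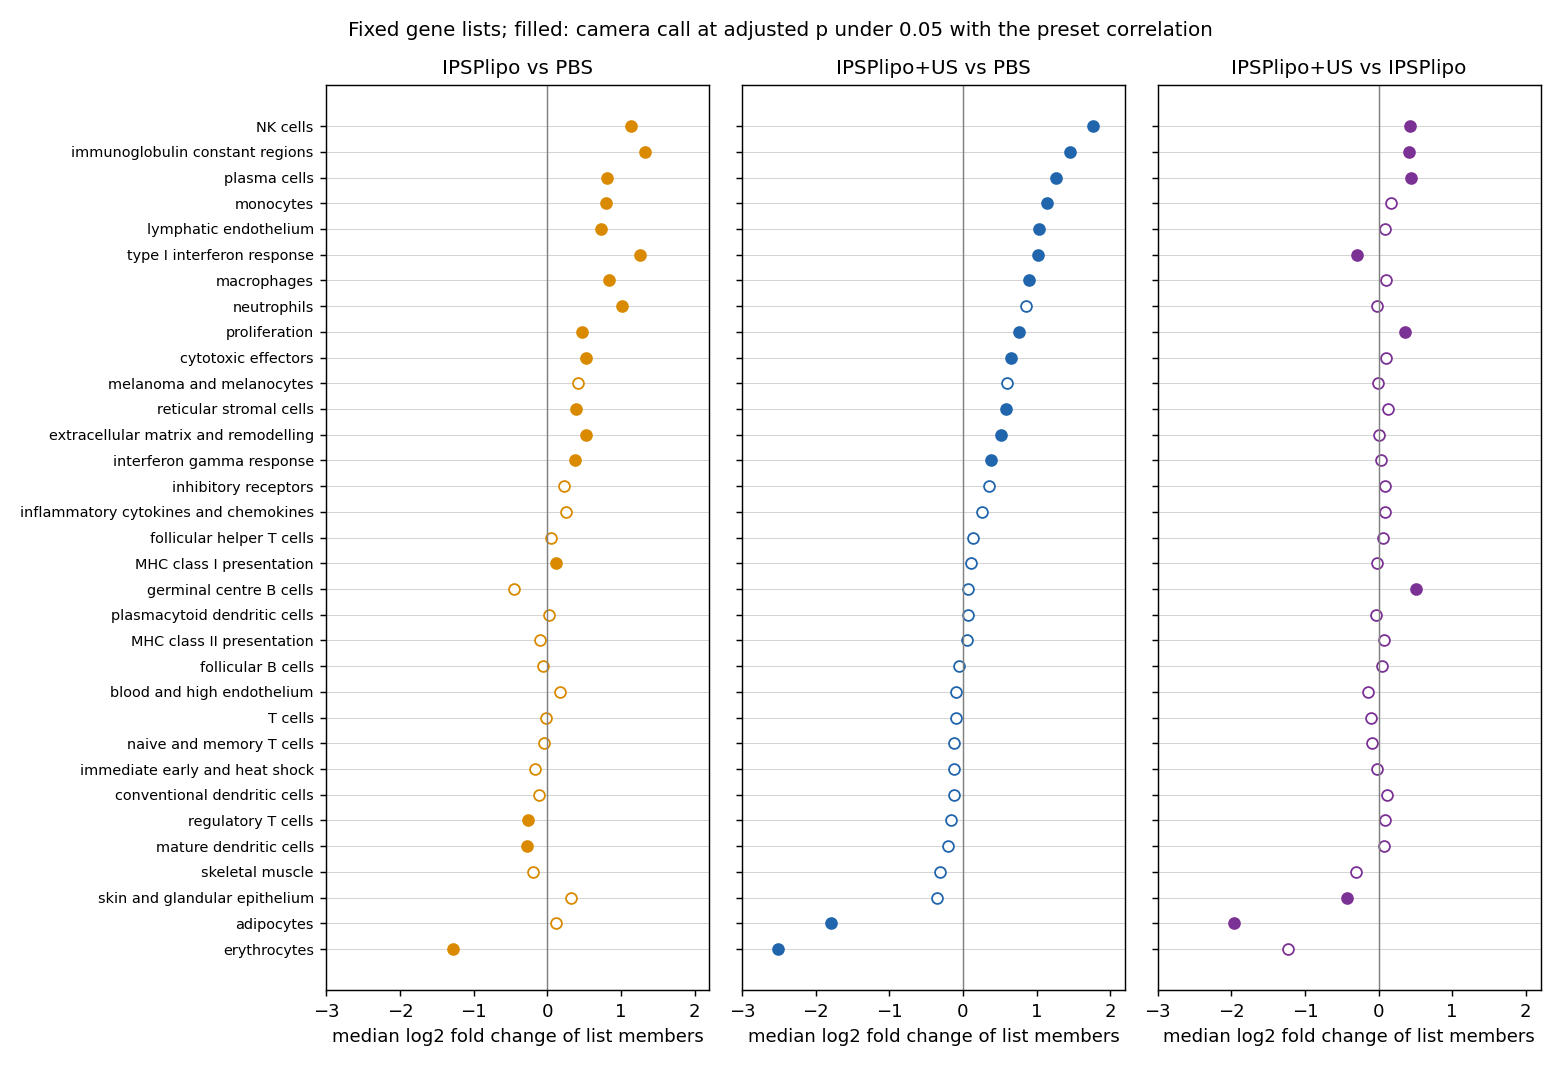
Each point is the median log2 fold change of the tested members of a gene list fixed before the data were examined, for the 3 comparisons. Filled points passed camera with the preset correlation at an adjusted p under 0.05, and no list passed with an estimated correlation. The natural killer cell median was 1.13 in IPSPlipo against PBS, 1.77 in IPSPlipo+US against PBS and 0.43 in IPSPlipo+US against IPSPlipo.

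The third comparison asked what the addition of US changed over IPSPlipo. Between IPSPlipo+US and IPSPlipo no gene passed the threshold (edgeR quasi-likelihood test, smallest adjusted p 0.965). Levels of Gzma were 17.0 ± 1.98 against 9.40 ± 4.62 CPM, of Jchain 605 ± 274 against 298 ± 170 CPM and of Igkc 1032 ± 330 against 643 ± 259 CPM, none of which passed (adjusted p = 0.965 for each). The log2 difference was 0.86 for Gzma with a 95% interval of 0.23 to 1.49 and 1.02 for Jchain with 0.15 to 1.89. For Gzmb it was 0.37 with an interval of -0.34 to 1.09, for Cd8a -0.19 with -0.52 to 0.14, and for Prf1 0.04 with -0.27 to 0.35. These intervals use the standard error with a normal distribution. They hold for a single gene and are not adjusted over the 21182 genes tested, so an interval without 0 is not a call. DESeq2 and limma-voom also called 0 genes. By edgeR 834 genes had an unadjusted p under 0.05, fewer than the share of 0.05 of the 21182 genes that chance gives. The libraries of the groups did not overlap for 586 genes, 2.77% of those tested, where chance gives 2.86%.

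Camera with the preset correlation called 8 lists in this comparison, none of which had a member past the threshold over all genes. Higher in IPSPlipo+US were the lists of plasma cells (median 0.44), immunoglobulin constant regions (0.42), natural killer cells (0.43), germinal centre B cells (0.51) and proliferation (0.36). Lower were type I interferon response (-0.29), adipocytes (-1.97) and skin and glandular epithelium (-0.43). With an estimated correlation their adjusted p-values lay between 0.693 and 0.843, and fry called no list (smallest adjusted p 0.543). The call of germinal centre B cells ended without PBS 4, IPSPlipo 1, 3 or 4 or IPSPlipo+US 3, whose mean log2 CPM on that list was 4.95 where the others of its group had 3.29 to 4.06. That of the type I interferon response ended without IPSPlipo 2, 3 or 4 or IPSPlipo+US 2, and that of skin and glandular epithelium without PBS 4, IPSPlipo 2, 3 or 4 or IPSPlipo+US 1, 3 or 4. Adjusted over the list alone, 1 plasma cell gene passed, Slamf7. With the adipocyte level as a covariate, which removes the change of the adipocyte list itself by construction, 3 of the other 7 calls remained, those of plasma cells, proliferation and type I interferon response. The smallest adjusted p-values in these lists were those of Slamf7, Fkbp11 and Mzb1 (1.27-, 1.86- and 1.88-fold), Ighg2b (1.98-fold), Klre1 and Ncr1 (1.65- and 1.53-fold), Eaf2, Nuggc and Gcsam (1.87-, 1.86- and 1.72-fold), Ccnb2, Ccnb1 and Plk1 (1.35-, 1.48- and 1.45-fold), Oas3, Oas2 and Mx1 (0.730, 0.683 and 0.775 of IPSPlipo), and Krt18 and Krt8 (0.355 and 0.383), none of which passed. Cidec was at 0.167 of its IPSPlipo level and Fabp4 at 26.5 ± 29.4 against 101 ± 78.6 CPM. Single libraries weighed on some of these values. Nuggc was at 31.4 CPM in IPSPlipo+US 3 and at 6.78 to 11.9 in the others of its group. In IPSPlipo+US 2 Cidec was at 14.8 CPM (0.198 to 1.14 in the others), Krt18 at 4.47 (0.102 to 0.518) and Krt8 at 5.68 (0.102 to 0.621). In IPSPlipo 2 Krt8 was at 10.8 CPM (1.21 to 4.49 in the others). The adipocyte list was at 4.97, 6.21, 3.79 and 4.21 log2 CPM in IPSPlipo 1 to 4, and its median was -1.28 without IPSPlipo 2 and -5.46 without IPSPlipo+US 2. The other lists had medians between -1.23 (erythrocytes) and 0.17 (monocytes).

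The 3 genes with the smallest p were the predicted gene AC102342.2 (4.04 ± 0.606 against 1.65 ± 0.397 CPM) and the immunoglobulin segments Ighv1-5 (51.2 ± 56.9 against 4.38 ± 2.47 CPM) and Ighv5-9-1 (4.65 ± 1.57 against 42.6 ± 46.4 CPM), which did not pass. Foxp3, Cxcl9, Cxcl10, Cd274, Lyve1, Mki67, Ifng and Pmel did not pass either, with adjusted p-values between 0.965 and 0.996. Without IPSPlipo+US 2, 1 gene passed, Cbr2, lower in IPSPlipo+US (log2 fold change -2.34, adjusted p = 0.0476), which was named after its values were seen.

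In the joint test of the 3 groups 977 genes passed. That count was 456 without PBS 2, 32 without PBS 3, 89 without PBS 4, 638 without IPSPlipo+US 2, 542 without IPSPlipo+US 3 and 318 without IPSPlipo+US 4, and 0 without both PBS 3 and PBS 4 or with the share of the most abundant identifier as a covariate.

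The comparisons against PBS shared their 4 control libraries. Of the 100 genes changed in IPSPlipo and the 2307 in IPSPlipo+US, 95 were changed in both, 78 higher in both and 17 lower in both, and 0 went opposite ways. Independent lists of these sizes would share 6.08 genes changed in the same direction. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.789, against 0.515 ± 0.0103 in 20 simulations of unchanged groups. These drew all 12 libraries, PBS included, gene by gene from the PBS means. A deviation of PBS 3 and PBS 4 shared by many genes was therefore absent, and shared controls may give more than simulated. The covariance of the fold changes was 0.224, against 0.0663 simulated, a difference of 0.158. With the PBS libraries split into pairs, each used for a single comparison, the overlap averaged 3.67 genes (0 to 21 over the splits). The correlation averaged 0.396 and the covariance 0.159. With PBS 1 and 2, 1 and 3, 2 and 3 or 2 and 4 for IPSPlipo, that comparison called 0 genes. No overlap was possible there. Where PBS 3 and PBS 4 served IPSPlipo, 778 and 25 genes were called, and 21 were shared. The average overlap therefore does not show how far the 95 genes rest on shared controls. Of the 2307 genes changed in IPSPlipo+US, 2305 had the same sign in IPSPlipo, with a median size of 0.44 on the log2 scale against 0.67, and 1767 (76.6%) had an unadjusted p under 0.05 there. Shared controls alone give part of this. In 20 simulations with IPSPlipo unchanged, a test added after the result was seen, 66.1 ± 0.662% of the genes called in IPSPlipo+US had the same sign and 6.72% an unadjusted p under 0.05. Libraries were again drawn gene by gene, so these shares leave out deviations of PBS libraries common to many genes. With a pair of PBS libraries for each comparison, 81.3% of 3634 called genes had the same sign where PBS 3 and PBS 4 served IPSPlipo+US, and 94.5% of 1312 and 94.9% of 759 where PBS 4 served it with PBS 2 or PBS 1. In the other 3 pairings, which called 54 genes at most, 100% did.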

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

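Tests of PBS 3 and PBS 4, of the most abundant identifier and of admixed tissue were chosen after the results were seen, and the tests of other splits and of GC content were set before theirs were. In each group of 4 libraries the highest or lowest value was marked where its gap to the next took most of the group's range. That marked 21 of 414 sets of values (5.07%), close to the 5% that chance gives, with 6 in PBS 1 and 6 in IPSPlipo+US 2.

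In PBS 1, Cd8a was at 110.0 CPM where the other PBS libraries had 158 to 167, Zap70 at 87.6 (111 to 116), Cd6 at 117 (142 to 145), Ly6c2 at 25.2 (40.6 to 41.9) and Pacsin1 at 32.6 (46.3 to 47.4), and Cd79b was higher at 373 CPM (307 to 315). In PBS 4, Cd300e was at 1.02 CPM (0.381 to 0.443) and Lipe at 82.1 (27.4 to 36.6). In IPSPlipo 1, Cd79b was at 338 CPM (399 to 408), Igtp at 59.8 (81.0 to 82.0) and Sbsn at 0.920 (1.73 to 1.83). Cxcl9 was at 47.6 CPM in IPSPlipo 3 (25.3 to 27.1). In IPSPlipo+US 2, Cidec was at 14.8 CPM (0.198 to 1.14), Krt18 at 4.47 (0.102 to 0.518), Krt8 at 5.68 (0.102 to 0.621), Ppbp at 0.631 (0.0988 to 0.104) and Fcrla at 77.3 (102 to 106). The mitochondrial share of that library was 0.954% (1.19% to 1.23% in the others). Slamf7 was at 80.6 CPM in IPSPlipo+US 1 (74.6 to 75.6) and Bub1 at 54.0 in IPSPlipo+US 3 (27.1 to 31.3).

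Other splits of the libraries were used to ask about a chance division. In both comparisons with PBS the real split gave the most genes. These comparisons share their PBS libraries, and 1 of 35 is the smallest share their splits can give, so chance is not excluded. For IPSPlipo+US against PBS, 1 of 35 splits of the 8 libraries, the real one, gave 2307 genes, and the highest of the others gave 1. For IPSPlipo against PBS, 1 of 35 splits gave as many as the real 100, and the highest other gave 1. For the joint test of the 3 groups, the real grouping and randomly drawn ones made up 60 splits, not all that are possible. Of these 60, 1, the real one, gave as many as the real 977. The highest other gave 537, with PBS 2, PBS 3, PBS 4 and IPSPlipo 1 in a group. For IPSPlipo+US against IPSPlipo the real count was 0, which all 35 of 35 splits reach by construction, so that the splits say nothing about chance there. The highest other, a split that put IPSPlipo 1, IPSPlipo 2, IPSPlipo+US 1 and IPSPlipo+US 3 together, called 76 genes. A different split, with IPSPlipo 1, IPSPlipo 4, IPSPlipo+US 2 and IPSPlipo+US 4 together, called 48. Whether these mark a structure of the libraries other than their groups was not tested.

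The first pattern weighed was the 2307 genes changed between IPSPlipo+US and PBS. A trend with GC content or exon length as the whole cause was argued against, since 1713 genes were called in the same direction before and after a correction for both. PBS 3 and PBS 4 as the source stayed open. Genes called with these and a pair of IPSPlipo+US libraries kept 0.400 of their median log2 fold change in the other libraries (0.311 to 0.482 over 6 splits). Selection of called genes alone may lower that share. In those other libraries 84.0% to 96.2% of them went in the same direction, with medians of 0.27 to 0.45. Most of them thus also differed that way where PBS 3 and PBS 4 were outside the comparison. All 12 libraries entered the filter, scaling and estimate of the spread behind the calls. Genes are not independent replicates, and the SD over genes (0.527 to 0.584) does not measure the error of a median. Neither value therefore decides the question. The share of counts on the most abundant identifier cannot be told apart from the treatment. As a covariate it ended all calls and left 0.517 of the median change of these genes (0.35 from 0.67 on the log2 scale, median standard error 0.216 from 0.165), and the group explained 0.676 of its variance between PBS and IPSPlipo+US.

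The second pattern was the 12 immune, stromal and proliferation lists called higher in IPSPlipo+US than in PBS, none of which held with an estimated correlation (smallest adjusted p 0.274). Less admixed fat and blood in the treated nodes would raise all resident cell types alike, but the T cell list had a median of -0.0920 (SD 0.372 over its genes) where the macrophage list had 0.90. Without PBS 3 and PBS 4, 12 of 12 lists kept at least 0.5 of their median, though the call of lymphatic endothelium ended (adjusted p = 0.0617). The lists had been called with PBS 3 and PBS 4 included, and the remaining libraries had entered those calls. A kept median is therefore in part given by the selection of the lists, and PBS 3 and PBS 4 as the only source stayed open. A GC or length trend was argued against, since 12 of 12 lists kept at least 0.5 of their median after correction. With the share of the most abundant identifier as a covariate 8 of 12 did and stayed called with the preset correlation, while the medians of monocytes (1.15 to 0.29), reticular stroma (0.58 to 0.17), matrix (0.52 to 0.20) and lymphatic endothelium (1.03 to 0.39) fell further and their calls ended, so that a change tied to this share stays open. A treatment effect is a hypothesis here, and this covariate, which follows the groups, was the only test of it apart from that share.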

How the results depend on the processing

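PBS 3 and PBS 4 left out, both covariates, the GC and length correction and thinning were chosen after the data were seen; the other alternatives were set before. Unless said otherwise, the cause of a change was not tested.

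Genes changed between IPSPlipo and PBS numbered 100, and 500 without a low-count filter, 1000 with DESeq2, 6 with limma-voom, 52 at a fold of at least 2, 625 with the adipocyte covariate and 180 after GC and length correction. They numbered 0 by edgeR without PBS 3 and PBS 4 and with the share of the most abundant identifier as a covariate (2058 and 2123 at an unadjusted p under 0.05; only edgeR was run there), where the 100 genes kept 0.894 and 0.798 of their median log2 fold change. For IPSPlipo+US against PBS the count of 2307 became 3602 with DESeq2, 633 at a fold of at least 2, 4 without PBS 3 and PBS 4 (Gzma, Hist1h3b, Hist1h3h and Iglv1), 0 with the share covariate by edgeR (2085 unadjusted) and 134 with the adipocyte covariate; the 2307 genes kept 0.794, 0.517 and 0.760 of their median in the last 3. Fewer libraries and a covariate that follows the groups both widen the errors. The genes were chosen on the same libraries, which favours a kept direction and size. The count of 0 between IPSPlipo+US and IPSPlipo was 0 in all settings run but without IPSPlipo+US 2, where Cbr2 passed. For any group, 977 became 1491 without a filter, 2528 with DESeq2, 638 with limma-voom, 360 at a fold of at least 2, 0 without PBS 3 and PBS 4, 0 with the share covariate and 367 with the adipocyte covariate.

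With the replicate number as a block the edgeR counts were 0 for IPSPlipo against PBS and 1124 for IPSPlipo+US against PBS. They were 0 for IPSPlipo+US against IPSPlipo and 87 for any group. The comparisons at 0 had 3064 and 678 genes at an unadjusted p under 0.05. The 678 are fewer than the share of 0.05 of the 21182 genes that chance gives. The numbers did not pair the libraries. Correlations of same-numbered libraries ran from -0.145 to 0.128, and 2 of 12 libraries correlated best with their own number.

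With each library left out in turn, the counts ranged from 0 (without PBS 2 or PBS 3, where 3627 and 3010 had an unadjusted p under 0.05) to 245 (without IPSPlipo 2), with 230 without PBS 1, 8 without PBS 4, 200 without IPSPlipo 1, 9 without IPSPlipo 3 and 2 without IPSPlipo 4, for IPSPlipo against PBS. They ranged from 996 (without IPSPlipo+US 4) to 2969 (without PBS 1), with 1001 without PBS 3, 1012 without PBS 4, 1477 without IPSPlipo+US 1 and 1376 without IPSPlipo+US 3, for IPSPlipo+US against PBS. They ranged from 0 to 1 for IPSPlipo+US against IPSPlipo, and from 32 (without PBS 3) to 1149 (without PBS 1) for any group, with 456 without PBS 2, 89 without PBS 4, and 638, 542 and 318 without IPSPlipo+US 2, 3 and 4.

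Lists called fell from 17, 14 and 8 to 0, 0 and 0 with an estimated correlation, and from 8 to 3 with the adipocyte covariate for IPSPlipo+US against IPSPlipo, where the call of the adipocyte list ends by construction. Reversed were Clmn (log2 fold change 0.0426), Lat (0.132) and Ier2 (0.0560) in IPSPlipo+US against PBS with the share covariate, the erythrocyte list in IPSPlipo against PBS without PBS 3 and PBS 4 (median 0.33), and the test direction of the skin and glandular epithelium list in IPSPlipo+US against IPSPlipo with the adipocyte covariate (median -0.0615). Of the 27 named calls in IPSPlipo against PBS, 0 were kept without PBS 3 and PBS 4, with the share covariate, the block or limma-voom, or without PBS 2, PBS 3 or IPSPlipo 4, and 27 with either other scaling. Of the 86 in IPSPlipo+US against PBS, 0 were kept with the share covariate, 1 without PBS 3 and PBS 4 (Gzma), 20 with the adipocyte covariate, 50, 51 and 52 without IPSPlipo+US 4, PBS 3 and PBS 4, 59 with the block or without IPSPlipo+US 3, 63 with limma-voom or without IPSPlipo+US 2, and 65 and 68 without IPSPlipo+US 1 and PBS 2. The overlap of 95 genes was 3.67 on average with the PBS libraries split and 568 at an adjusted p under 0.1. Several of these splits called 0 genes in IPSPlipo against PBS, so that no overlap was possible in them. Thinning to equal depth gave 127 and 2251 genes, 95 and 2021 of them among the 100 and 2307.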

Other observations

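Gene families were screened after the data were seen, and the tests of single families below were chosen from that screen. Of 60 tested histone genes, 52 rose in IPSPlipo+US against PBS, with a median log2 fold change of 1.28, and 16 rose in IPSPlipo against PBS, with a median of 0.91. Between IPSPlipo+US and IPSPlipo the median was 0.40 and none passed. Of 17 genes of the interferon-inducible Ifi family, 13 rose in IPSPlipo+US (median 1.12), and of 12 Toll-like receptor genes, which sense microbial molecules, 6 rose (median 0.74). Of 23 Clec genes, many of them lectin receptors of myeloid cells, 8 rose and 1 fell (median 0.64). Of 97 genes whose symbols begin with Rp, most of them ribosomal proteins, 37 rose (median 0.30). Of 51 joining segments of the T cell receptor alpha chain, 7 fell and 0 rose (median -0.55). With the share of the most abundant identifier as a covariate these medians were 0.54 for Ifi genes, 0.47 for Toll-like receptors, -0.07 for Clec genes, 0.22 for Rp genes and -0.37 for the joining segments, so that the sign of the Clec median turned. Without PBS 3 and PBS 4 they were 0.83, 0.44, 0.43, 0.20 and -0.58.

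The screen covered 147 families per comparison. Camera with the preset correlation called 14 higher and 6 lower in IPSPlipo+US against PBS, 13 and 7 in IPSPlipo against PBS, and 4 and 2 in IPSPlipo+US against IPSPlipo. With an estimated correlation 0 were called in each, with smallest adjusted p-values of 0.420, 0.192 and 0.885. In IPSPlipo+US against PBS the adjusted p with an estimated correlation was 0.494 for histones, 0.569 for Ifi genes, 0.494 for Toll-like receptors, 0.711 for Clec genes, 0.631 for Rp genes and 0.569 for the joining segments.

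The third pattern weighed was the rise of histone genes, most of whose transcripts lack a poly(A) tail and are made during DNA replication. For carry-over of RNA without a tail, small nuclear, nucleolar and Cajal body RNA genes were read, which had a median log2 fold change of -0.154 (SD 0.621 over 240 genes). That argues against carry-over only if these RNAs are carried over as histone transcripts are. Whether they are was not tested. A GC or length trend was argued against, since the histone median was 1.30 after correction. Histone and proliferation levels moved together within groups over 12 libraries (r = 0.957, exact permutation p = 0.000289, rho = 0.860, exact permutation p = 0.00282). Without IPSPlipo+US 1 and IPSPlipo+US 3, r was 0.906, and 1 relation was computed. More dividing cells may thus account for the rise. That relation does not test the difference between groups. No other list was set beside it, so it may not be particular to proliferation. Without PBS 3 and PBS 4 the histone median was 1.13, and with the share of the most abundant identifier as a covariate 1.10.

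Protein-coding genes higher in IPSPlipo+US than in PBS had a median exon length of 3548 nucleotides and a median GC content of 45.7%, and lower genes 5995 nucleotides and 54.3%, against 4396.5 and 49.8% over the tested protein-coding genes.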
